A study of Mus musculus with 26 samples.

How the data were processed

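Endothelial cells positive for CD31 and CD146 were sorted from digested tissue, and picogram amounts of total RNA were amplified and labelled with the Affymetrix WT Pico kit, per the labels' protocols. The 26 arrays fall into 9 groups of 2 to 5. All animals were female, per the labels, and aged 4-6 months, or 3-4 months for 16.113 tumours. The labels number the replicates but do not state whether each came from its own animal.

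The values used are the deposited log2 expression values per probe set, normalized and summarized by the authors. Affymetrix Expression Console and limma are named in the submitters' processing notes, without versions, and the normalization method is not given in the sources used here. The table held 65535 probe sets with values from 1.40 to 14.34. Probe sets run in order of their identifiers and end there, so most of the genome's genes were not analysed here. Of the 5109 genes with a probe set of their own, 1292, 1074, 1716, 789 and 210 lie on chromosomes 1, 10, 11, 12 and 13, 20 on others and 8 could not be placed. Exact values recurred between arrays within 4 sets (MCA313 tumour, J558L tumour, J558L kidney and 16.113) and almost never between them, so these sets appear to have been normalized separately. Array medians were 5.78 to 5.88, 6.42 to 6.46, 6.33 to 6.40 and 5.62 to 5.79 in these sets. Levels were therefore not compared between sets. The planned test of J558L tumour against kidney without induction was not made for this reason, whereas differences of responses formed within sets were tested.

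Probe sets were assigned to genes by the annotation of the array's probes. Of the annotated symbols 4618 were current in the RefSeq table of the GRCm38.p6 assembly, 494 were synonyms and 8 had no match. Probe sets with several symbols (766) or none (10912) were not used for genes. Of a gene's probe sets (median 10) the one with the highest mean over all 26 arrays stood for the gene. A gene was kept if that probe set exceeded the array's 50th percentile of all probe sets in at least 2 arrays, which left 4386 genes. The probe sets of a gene read different exons and did not always move together, so the share that moved the same way is given for genes past the test where it was at most 2 in 3. Background was not measured. For named genes past the test, a log2 change with a group mean below the array medians is given as fitted and its size called uncertain. For arrays the precision is limited by their number.

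A linear model with 9 group means was fitted to all 26 arrays in limma 3.58.1 (R 4.3.3), with contrasts and moderated two-sided tests and the Benjamini-Hochberg correction over the 4386 genes of each comparison at 0.05. All groups shared the estimate of spread because several hold 2 arrays. The 9 comparisons were each time point or T cell group against its control, 48 h against 24 h, and differences of responses between tumour and kidney and between models. Lists of genes were tested with camera at a preset correlation of 0.01, corrected over the lists of a comparison. Of 30 lists 16 had at least 3 measured genes, and 99 of the 444 listed genes were measured. The call of the basement membrane and tip cell lists in kidney and of the GTPase list in 16.113 held with an estimated correlation and no other list call did.

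Groups, comparisons, lists and most alternatives were fixed before the data were examined, as was the choice of genes to name. These were the 10 largest rises and falls past the test whose replicates did not overlap, up to 4 members per list past the test (or up to 2 of the largest when none passed), and 18 check genes, 4 of which were measured. Genes outside that choice are said to be chosen after their values were seen. Alternatives were no filter, a stricter filter (75th percentile), quantile normalization of all arrays, the average of a gene's probe sets, a variance prior with trend and robust estimation, array weights, the replicate number as a block (statmod 1.5.0), and a fit of the arrays of the tumour models compared. For lists, the variance prior with trend had no robust form. Each array was left out in turn.

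The procedure was tested on simulated data with 200 of 4386 genes changed. For MCA313 at 24 h it recovered 30% of genes changed by 2-fold and 88% changed by 4-fold. For J558L tumour these shares were 54% and 78%, for J558L kidney 46% and 86%, and for 16.113 50% and 94%. For the difference between MCA313 and J558L they were 16% and 66%. Between 2.50% and 6.87% of called genes were unchanged ones. Every group was simulated with the same spread per gene and genes were drawn independently, so these shares do not cover groups that differ in spread. Each recovery share rests on 50 genes. The median standard error was 0.318 for both MCA313 at 24 h and J558L tumour, so their shares do not show a difference in power.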

Results

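Gene expression was measured on microarrays in 26 samples of endothelial cells sorted by CD31 and CD146 from mice carrying 1 of 3 tumours. MCA313 tumours grew in mice whose endothelial cells alone carried the interferon gamma (IFNγ) receptor, and the tumour cells were left uninduced (3 arrays) or made to release IFNγ for 24 h (2 arrays) or 48 h (2 arrays). J558L tumours grew in Rag-deficient mice with the receptor on all cells; endothelium was taken from the tumour without induction (2 arrays) and after 24 h of an IFNγ-GFP fusion (3 arrays), and from the kidney of J558L-bearing mice without induction (3 arrays) and after 24 h (3 arrays). 16.113 tumours, also in Rag-deficient mice, were sampled 120 h after transfer of T cells that could make IFNγ (competent, 3 arrays) or could not (deficient, 5 arrays). The number of arrays limits the precision. The table used here held part of the array, so that almost all of its genes lie on chromosomes 1, 10, 11, 12 and 13, and 4386 genes were tested. Cxcl9, Cxcl10, Cd274 and the class II histocompatibility genes were not analysed here, and statements on gene groups cover their measured members. Changes are given as log2 fold change ± standard error, with p adjusted over all genes tested in limma.

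Pecam1, which encodes the sorting marker CD31, was high in every group, with means between 13.51 and 13.95 on the log2 scale. Its changes at the brightest probe set lay between -0.12 and -0.04 in the 5 comparisons with a control group, and none passed the test. In MCA313 tumours 20 and 19 of its 21 probe sets were lower at 24 h and 48 h, with medians of -0.24 and -0.23. Ifngr1, which encodes the ligand-binding chain of the IFNγ receptor, changed by -0.31 to 0.42, with none past the test. Ifng itself had group means between 5.35 and 6.49, with no change past the threshold.

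The first comparison asked what 24 h of IFNγ does to tumour endothelium when the receptor sits on endothelial cells alone. In MCA313 tumours, Ifi205 and Ifi207, interferon-inducible genes of the Ifi200 family, rose. Ifi205 (probe set 17230116) rose by 4.28 ± 0.40, 19.4-fold, from 7.53 ± 1.14 (SD, n = 3) to 11.81 in both arrays at 24 h (adjusted p = 4.76e-06), and Ifi207 by 3.15 ± 0.39. Irf4, a transcription factor of the interferon regulatory factor family, rose by 3.39 ± 0.52, with all 11 of its probe sets higher. Ctla4, known as an inhibitory receptor of T cells, rose by 3.73 ± 0.58 (adjusted p = 0.00113), from 5.34 ± 1.25 (SD, n = 3) to 9.06 ± 0.50 (SD, n = 2). The immune receptor genes Fcgr4 and Slamf8 rose by 3.67 and 2.28, and the feedback inhibitor of cytokine signalling Socs3 and the transcription regulator Id2 by 1.63 and 1.97 at the brightest probe set. Of their probe sets 4 of 6 and 2 of 4 were higher, with medians of 0.11 and 0.97. Gdap10 rose by 2.55 and the carbonic anhydrase gene Car4 by 2.16. The measured probe sets of C130026I21Rik and Calhm6, which rose by 4.91 and 4.36 at the brightest probe set, had a median change of 0.27 (4 of 6 higher) and 0.49. The genes that fell were Hmmr (-2.15), the helicase gene Helb (-1.92), the elastic fibre gene Fbln5 (-1.76), Acsf2 (-1.62), Bicd2 (-1.48) and the ETS factor gene Etv4 (-1.39). For Irf4, Ctla4, Fcgr4, Calhm6, C130026I21Rik and Hmmr the lower group mean lay below the array medians and may be background, so the sizes of these changes are uncertain.

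Across all genes, 30 passed at 24 h, 24 higher and 6 lower, and 479 had an unadjusted p under 0.05 where chance would give 219.3. Of the 5 measured interferon-inducible GTPases, which act against intracellular pathogens, Irgm1 rose, by 1.56 ± 0.34 (adjusted p = 0.0328), and all 5 passed when adjusted over the list alone. As a list they shifted upward (camera in limma, adjusted p = 2.61e-08; adjusted p = 0.104 with an estimated correlation). Of 5 interferon signalling genes Socs3 rose at its brightest probe set, and 2 passed when adjusted over the list alone; Irf1, a direct IFNγ target, stood at +1.02 ± 0.24 with adjusted p = 0.0527. That list also shifted upward (adjusted p = 7.59e-06; adjusted p = 0.104 with an estimated correlation). The 8 cell cycle genes shifted downward as a list (adjusted p = 0.0142; adjusted p = 0.260 with an estimated correlation), with none past the test singly or adjusted over the list alone, Birc5 at -1.60 and Rrm2 at -1.40. That call ended without 24 h replicate 2. The same held for 8 tip cell genes, known from sprouting vessels (adjusted p = 0.0394; adjusted p = 0.158 with an estimated correlation), where 2 passed when adjusted over the list alone and Unc5b and Nrp2 stood at -0.92 and -0.72. The tip cell call ended without control replicate 1 or 3 or 24 h replicate 2, with a stricter filter, with averaged probe sets and with the MCA313 arrays alone. The count was 12 without 24 h replicate 2, 14 without control replicate 1, 49 without control replicate 2 and 1 when the MCA313 arrays were fitted alone, and 47, 60 and 140 with a stricter filter, with array weights and with averaged probe sets. Of the 19 genes named here as past the test, 7 stayed so whichever 1 of the 5 arrays was left out, and none of the 6 that fell did; Ctla4 had adjusted p = 0.0734 without 24 h replicate 2 and 0.205 with the MCA313 arrays alone.

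At 48 h in MCA313 tumours, 60 genes passed against the same controls, 40 higher and 20 lower, with 560 at an unadjusted p under 0.05. Ctla4 stood 4.71 ± 0.58 above control (adjusted p = 9.50e-05), at 10.05 ± 0.92 (SD, n = 2). Ifi205 and Ifi207 were higher by 4.27 and 3.35, Irf4 by 3.04, Id2 by 2.07 and Gdap10 by 2.37. Fcgr4 was higher by 3.33, Socs3 by 1.17 (4 of 6 probe sets higher, median 0.26), Calhm6 by 4.01 (2 of 3, median 0.88) and C130026I21Rik by 4.79 (median 0.75). Ccl5, a chemokine that attracts T cells, rose by 2.51 ± 0.52 (adjusted p = 0.0196), Irf1 by 1.06 ± 0.24 (adjusted p = 0.0336), Irgm1 by 1.37 and the microRNA gene Mir329 by 2.48. Sele, which encodes the leukocyte adhesion molecule E-selectin, fell by 2.24 on the log2 scale, with all 13 probe sets lower (adjusted p = 0.0249). The histone gene H2bc3 (-1.93), the purine synthesis gene Atic (-1.71), Plekhg3 (-1.88), Zfp322a (-2.56), Mipol1 (-2.56), Tmem220 (-2.48), Casq1 (-1.66), Rab34 (-1.66) and Wscd1 (-1.56) also fell at the brightest probe set. Of the probe sets of Mipol1 12 of 20 pointed down, of Casq1 7 of 12, of Rab34 9 of 14 and of Wscd1 10 of 15. Sizes are uncertain, with the lower mean below the array medians, for Irf4, Ctla4, Fcgr4, Calhm6, C130026I21Rik, Mir329, Zfp322a, Mipol1, Tmem220 and Rab34.

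The interferon-inducible GTPases shifted upward at 48 h (1 of 5 rose over all genes, 5 adjusted over the list alone; camera adjusted p = 1.78e-06; adjusted p = 0.151 with an estimated correlation), as did interferon signalling (2 of 5 rose, 2 adjusted over the list alone; adjusted p = 1.42e-04; adjusted p = 0.151 with an estimated correlation). Downward shifts had adjusted p = 0.0473 each for 8 cell cycle, 8 tip cell and 3 endothelial identity genes, none of which fell singly; Birc5 stood at -2.93 ± 0.78 with adjusted p = 0.0632, Top2a at -1.42, Unc5b at -0.93 and Nrp2 at -0.75. With an estimated correlation the adjusted p was 0.263, 0.151 and 0.151, and adjusted over the list alone 1, 2 and 1 members passed. The count was 14 without 48 h replicate 1, 19 without control replicate 1 and 4 with the MCA313 arrays alone, and 174 with averaged probe sets; 7 of the 24 named genes, Ctla4 among them, stayed past the test whichever array was left out, though Ctla4 had adjusted p = 0.0896 with the MCA313 arrays alone. The 3 downward list calls ended without control replicate 1 or 3 or 48 h replicate 1, with a stricter filter and with the MCA313 arrays alone, and Sele lost its call without control replicate 1 or 2 or 48 h replicate 1. Control replicates differed in interferon genes: Ifi205 read 6.98, 6.76 and 8.83 and Gm12250 read 8.03, 9.81 and 10.48 in control replicates 1, 2 and 3.

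Between 24 h and 48 h, 3 genes differed: Rab34 (-1.93 ± 0.34), Mgat4e (+1.39 ± 0.24) and Mir329 (+1.93 ± 0.35), each with adjusted p = 0.0287, and 166 had an unadjusted p under 0.05. The other probe sets gave Rab34 and Mgat4e little support: 9 of 14 and 4 of 6 pointed the same way, with medians of -0.17 and 0.14 over all of them. All 3 genes had a mean below the array medians at 1 of the time points, so the sizes are uncertain. None of the 3 stayed past the test in all fits without 1 array. The count was 0 without 24 h replicate 2, 1 without 48 h replicate 1 and 7 without 48 h replicate 2. It was also 0 with a trended variance prior, with array weights and with the MCA313 arrays alone, and 1 with a stricter filter or averaged probe sets. Across the 4386 genes, the changes at 24 h and 48 h had r = 0.686. Because both use the same controls, unchanged groups simulated with that design gave r = 0.400, and the covariance of 0.194 exceeded the simulated 0.0680 by 0.126.

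**Figure D1:**
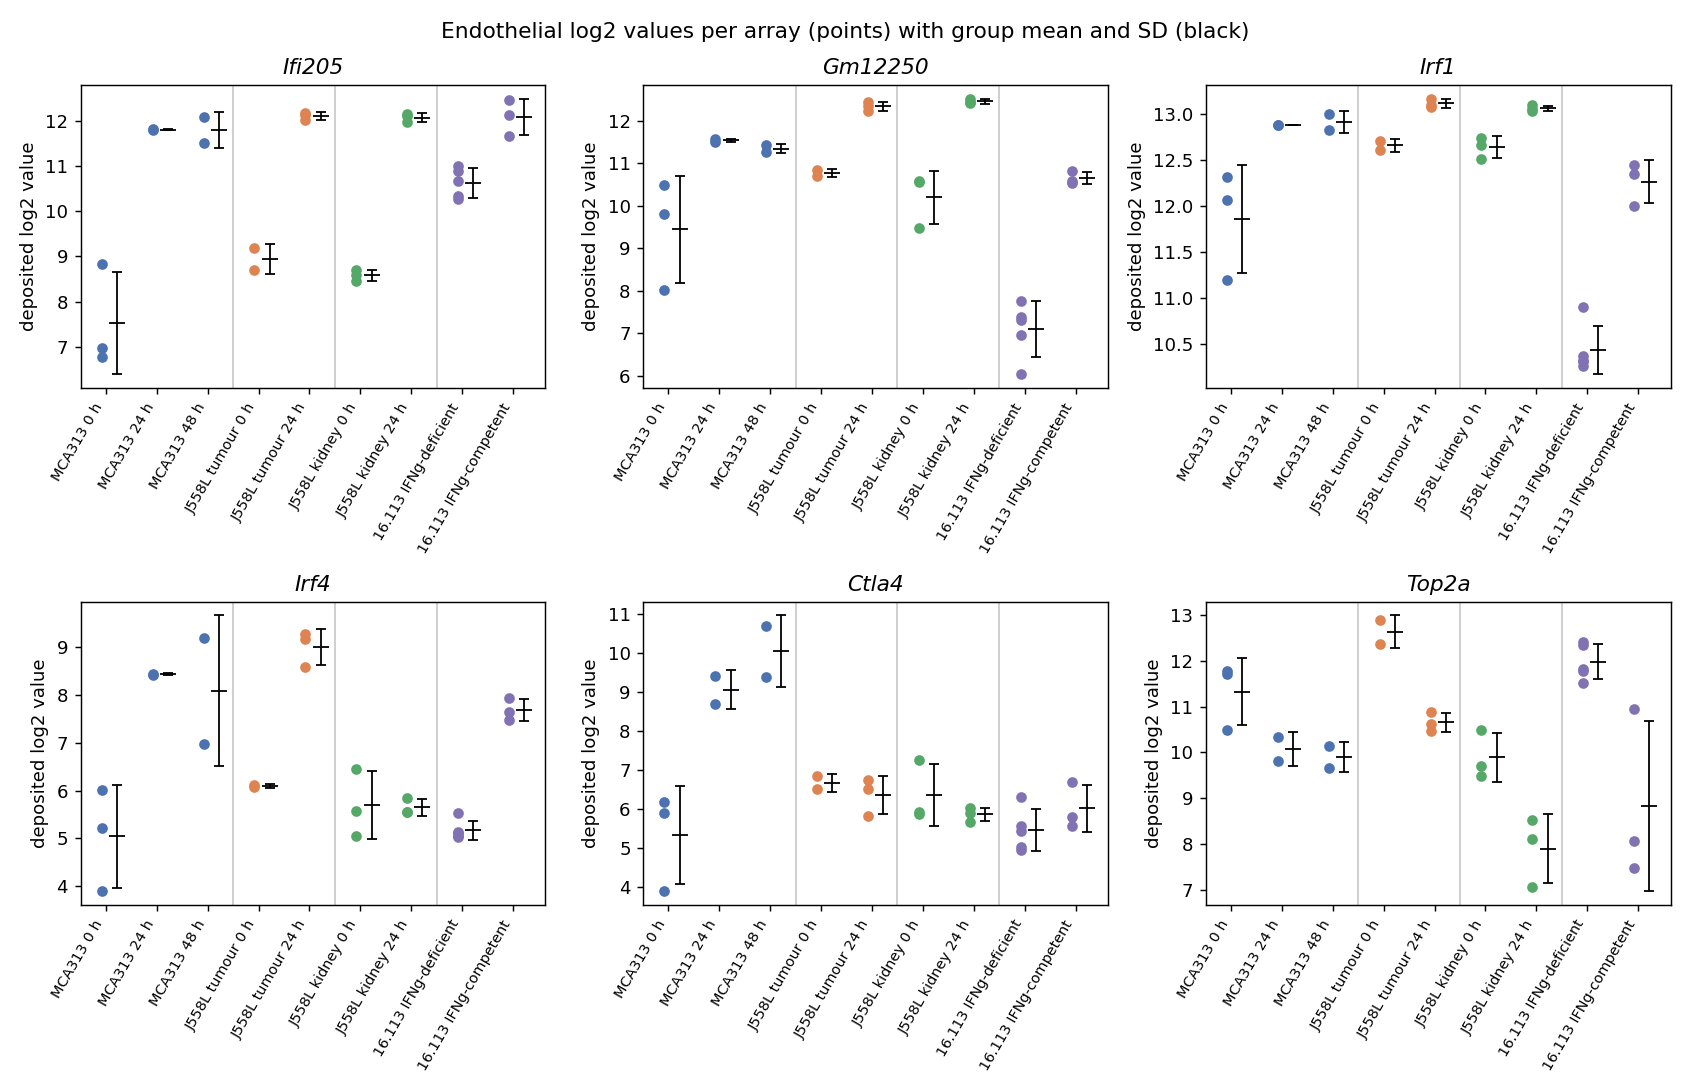
Log2 values as deposited (vertical axis) of 6 genes in each array (points) of the 9 groups (horizontal axis), with the group mean and SD in black. Grey lines part the 4 sets of arrays that appear to have been normalized separately, between which heights cannot be compared. Ctla4 means in MCA313 tumours were 5.34, 9.06 and 10.05 at 0, 24 and 48 h, and Top2a in competent replicate 1 of 16.113 (10.94) lay apart from replicates 2 and 3 (7.47 and 8.07).

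In J558L tumours, with the receptor on all cells, 24 h of IFNγ-GFP raised Ifi205 by 3.17 ± 0.40 (adjusted p = 6.68e-04), from 8.94 ± 0.34 (SD, n = 2) to 12.11 ± 0.08 (SD, n = 3). Irf4 rose by 2.90 ± 0.52, Ifi207 by 2.37, Slamf8 by 2.14, Id2 by 1.90 ± 0.26 (adjusted p = 9.20e-04) and Socs3 by 1.25. The nuclear body gene Sp140 rose by 2.19, the kinase gene Nuak1 by 2.16, Gdap10 by 1.93, the lipoxygenase gene Alox12 by 1.82 and C130026I21Rik by 3.14 (4 of 6 probe sets higher, median 0.83). The exonuclease gene Exo1 (-2.61), Fbxo5, an inhibitor of the anaphase-promoting complex (-2.57), and the histone gene H2bc3 (-2.46, 2 of 3 probe sets lower) fell. Emid1 (-1.59), Hecw2 (-1.58), 2810408I11Rik (-1.61), the Bcl2 family gene Bok (-1.29) and Nucks1 (-0.90) fell as well. The sizes for Irf4, Exo1, Fbxo5 and 2810408I11Rik are uncertain, since their lower mean lay below the array medians. Irf1 (+0.46 ± 0.24, adjusted p = 0.721), Gm12250 (+1.57 ± 0.50, adjusted p = 0.239) and Irgm1 (+1.05 ± 0.34) did not pass.

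In total 24 genes passed in J558L tumours, 16 higher and 8 lower, with 357 at an unadjusted p under 0.05. The 5 interferon-inducible GTPases shifted upward, 0 past the test over all genes and 4 adjusted over the list alone (camera adjusted p = 2.87e-05; adjusted p = 0.165 with an estimated correlation). Interferon signalling (1 of 5 rose, Socs3, and 1 adjusted over the list alone; adjusted p = 0.00128) and 3 antiviral genes of the type I interferon response (0 rose, 3 adjusted over the list alone; adjusted p = 6.02e-04) shifted the same way, with adjusted p = 0.184 and 0.124 with an estimated correlation. The 8 cell cycle genes shifted downward (adjusted p = 1.37e-05; adjusted p = 0.0782 with an estimated correlation), 0 past the test over all genes and 6 adjusted over the list alone; Birc5 stood at -2.05 ± 0.78 (adjusted p = 0.408) and Top2a at -1.98 ± 0.67 (adjusted p = 0.283). The count was 3 without control replicate 1, 13 without any 1 of the 24 h arrays, 61 with the J558L arrays alone, 109 with averaged probe sets and 127 with array weights. Of the 19 named genes, Ifi205 and Id2 stayed past the test whichever array was left out.

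Kidney endothelium from J558L-bearing mice changed as well, in 139 genes, 72 higher and 67 lower, with 602 at an unadjusted p under 0.05. Calhm6 rose by 6.46 ± 0.67 at its brightest probe set, from 3.58 ± 0.52 to 10.04 ± 0.18 (SD, n = 3 each). The control level lay far below the array medians and may be background, so the size is uncertain; 2 of its 3 probe sets were higher, with a median of 1.24. Interferon-inducible genes followed: Ifi209 rose by 3.63, Ifi205 by 3.49 ± 0.36 (adjusted p = 6.78e-06), Ifi208 by 3.46, the Schlafen genes Slfn4 and Slfn9 by 2.84 and 2.40, and Sp140 by 2.59. The protease inhibitor genes Serpina3f and Serpina3g rose by 3.87 and 2.60 and the pyrophosphatase gene Ppa1 by 2.87. Of the GTPases Gm12250 (+2.25), Igtp (+1.22) and Irgm1 (+1.16) rose, and of the antiviral genes Cmpk2 (+0.81). Members of the Ifi200, Slfn, Serpina3 and Sp140 families resemble each other in sequence, so that a probe set may also read a relative of the gene it is assigned to.

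Genes that fell in the kidney included the vascular matrix genes Lama4 (-1.31 ± 0.17, adjusted p = 1.28e-04), Fn1 (-0.77) and Lamb1 (-0.63), and the chemokine receptor gene Cxcr4 (-1.37). Car4 fell by 2.60 on the log2 scale (adjusted p = 0.00159). The matrix gene Prelp (-1.76), the checkpoint gene Vsir (-1.21), Chd3 (-1.70), Nav3 (-1.70), Mmd (-1.94), Stau2 (-2.73, 13 of 23 probe sets lower), Tmem200a (-2.28) and the olfactory receptor gene Olfr1396 (-2.87 ± 0.30, 2 of 3 lower) fell too. For the lactate transporter gene Slc16a3 (-2.31) and for Rrm2 (-1.87), 4 of 11 and 6 of 14 probe sets pointed down. As for Calhm6, the lower mean lay below the array medians for Ifi208, Olfr1396, Rrm2, Slc16a3, Stau2 and Tmem200a, and these sizes are uncertain. Of 8 basement membrane and matrix genes 3 fell, 4 adjusted over the list alone, and the list shifted downward (camera adjusted p = 6.48e-05; adjusted p = 0.0301 with an estimated correlation). Of 8 tip cell genes 2 fell, Cxcr4 and Lama4, and 2 adjusted over the list alone (adjusted p = 0.00170; adjusted p = 0.0330 with an estimated correlation); Lama4 is in both lists. Upward shifts were found for the GTPases (3 of 5 rose, 5 adjusted over the list alone; adjusted p = 7.21e-06), antiviral genes (1 of 3, and 2 adjusted over the list alone; adjusted p = 0.00614) and chemokines (0 of 5, and 1 adjusted over the list alone; adjusted p = 0.0492), with Ccl5 at +1.63 ± 0.47 (adjusted p = 0.0624). With an estimated correlation their adjusted p was 0.130, 0.165 and 0.215. The chemokine call ended without control replicate 2 or 24 h replicate 1 or 2, with averaged probe sets and with the J558L arrays alone. The 8 cell cycle genes gave adjusted p = 0.0591 (1 fell, 2 adjusted over the list alone), and Irf1 stood at +0.42 ± 0.22 (adjusted p = 0.407). The count fell to 69 without control replicate 2, 77 without control replicate 3, and 91, 80 and 85 without 24 h replicates 1, 2 and 3, and was 242 with array weights and 277 with averaged probe sets; 16 of the 29 named genes stayed past the test whichever array was left out.

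The test of whether the 24 h response differed between J558L tumour and kidney called 1 gene, Olfr1396 (adjusted p = 0.0153), and 210 had an unadjusted p under 0.05. Olfr1396 read 3.33 to 3.58 in all J558L tumour arrays, against array medians of 6.42 to 6.46, where a fall could not be read. The call therefore restates the fall in kidney and shows no difference between the tissues, and it ended without tumour control replicate 1 and without 24 h tumour replicates 1 and 3. The basement membrane and matrix list differed, a call that ended with averaged probe sets (adjusted p = 0.00119; adjusted p = 0.0736 with an estimated correlation), with 2 of 8 genes adjusted over the list alone and Fn1 (+1.16 ± 0.26) and Lama4 (+1.13 ± 0.26) not past the test singly. Irf4 stood at +2.95 ± 0.70 (adjusted p = 0.194). With averaged probe sets or array weights 16 genes differed, and 3, 3, 5 and 4 did with a stricter filter, quantile normalization, a trended variance prior and the J558L arrays alone; with averaged probe sets Irf4 was among them (adjusted p = 0.00119), with a size left uncertain by its low control level in tumour. Averaging also called the matrix gene Fn1 (+1.75, adjusted p = 0.0283), although it ended the call of its list, and Fbxo5 (adjusted p = 0.0101) and Exo1 (adjusted p = 0.0424), both with a more negative change in tumour than in kidney.

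The comparison in 16.113 tumours addressed whether IFNγ from T cells acts like IFNγ released by engineered tumour cells. With competent T cells the interferon-inducible GTPases rose together against deficient T cells. Gm12250 rose by 3.56 ± 0.40, 11.8-fold, from 7.09 ± 0.66 (SD, n = 5) to 10.65 ± 0.15 (SD, n = 3) (adjusted p = 1.58e-05), Igtp by 2.73 ± 0.27 (adjusted p = 5.05e-06), Irgm2 by 2.27 and Irgm1 by 2.09. Irf1 (probe set 17249608) rose by 1.83 ± 0.20 with all 17 probe sets higher (adjusted p = 8.03e-06), Irf4 by 2.51, Ifi207 by 2.31, Serpina3f by 4.27 and Gm12185 by 4.66. The antiviral genes Xaf1, Cmpk2 and Rsad2 rose by 0.77, 0.58 and 0.44, Stat2 by 0.72 and Timp3, an inhibitor of matrix proteases, by 0.77. Tbx21, a transcription factor known from T and natural killer cells, rose by 2.69 with 5 of 7 probe sets higher, Akr1c14 by 2.95 with 9 of 14 and Calhm6 by 3.42 with 2 of 3. Top2a, a topoisomerase of dividing cells, fell by 3.15 on the log2 scale (adjusted p = 0.00135), as did the cell division genes Birc5 (-3.11), Dtl (-3.35), Cdc6 (-2.83), Rrm2 (-1.94) and the helicase gene Mcm6 (-1.09, all 20 probe sets lower). Gulp1 (-3.85), Serpinb2 (-3.78), Ints7 (-3.55), Asb3 (-3.32), Slc25a10 (-2.87), Sdc1 (-0.94, 7 of 12 probe sets lower), the netrin receptor gene Unc5b (-0.78), Igfbp3 (-0.45) and the connexin gene Gja1 (-0.58, 2 of 3 lower) also fell, as did Pdk2 (-3.57) with 6 of 12 probe sets lower. Sizes are uncertain, with the lower mean below the array medians, for Irf4, Gm12185, Tbx21, Akr1c14, Calhm6, Gulp1, Serpinb2, Asb3 and Pdk2.

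In 16.113 tumours 323 genes passed, 112 higher and 211 lower, with 945 at an unadjusted p under 0.05. All 5 GTPases rose, and 5 adjusted over the list alone (camera adjusted p = 3.21e-13; adjusted p = 0.0253 with an estimated correlation). All 3 antiviral genes rose, and 3 adjusted over the list alone (adjusted p = 0.00144; adjusted p = 0.111 with an estimated correlation), and 2 of 5 interferon signalling genes did, Irf1 and Stat2, and 3 adjusted over the list alone (adjusted p = 0.00423; adjusted p = 0.260 with an estimated correlation). Of 8 cell cycle genes 5 fell, 6 adjusted over the list alone (adjusted p = 3.51e-05; adjusted p = 0.0622 with an estimated correlation). Of 8 tip cell genes 2 fell, Unc5b and Igfbp3, and 3 adjusted over the list alone (adjusted p = 0.0284; adjusted p = 0.111 with an estimated correlation). The tip cell call ended without competent replicate 1 or 2 or deficient replicate 1 or 4, with a stricter filter and with averaged probe sets, and the interferon signalling call without competent replicate 1. The 3 competent arrays resembled each other least of all groups (r 0.847 to 0.889 across genes), and Top2a read 10.94, 7.47 and 8.07 in them against 11.98 ± 0.39 (SD, n = 5). The shared estimate of spread does not take up their wider spread, so the count of 323 may be too high. The count was 565 without competent replicate 1, 197 without competent replicate 3, 77 with array weights and 34, 25 of them higher, with the 16.113 arrays alone, where Top2a had adjusted p = 0.0720 and Irf1 and Gm12250 stayed past the test. Of the 33 named genes 26 stayed past the test whichever array was left out.

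**Figure D2:**
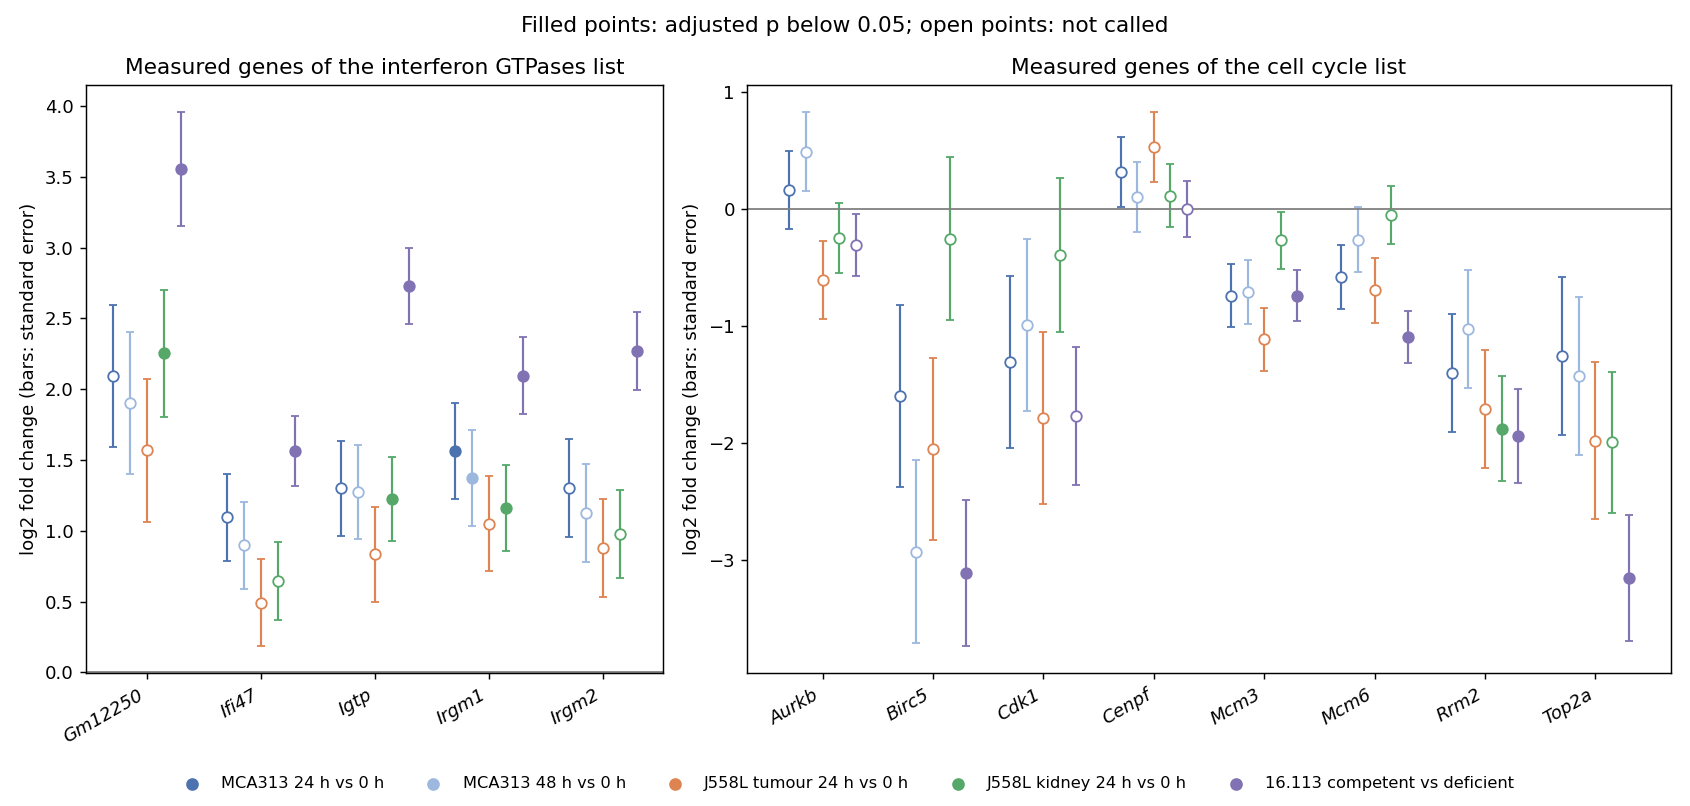
Log2 fold change (vertical axis) with standard error for each measured gene of the interferon-inducible GTPase list (left) and the cell cycle list (right) in 5 comparisons; filled points passed at an adjusted p of 0.05. All 5 GTPases passed in 16.113 tumours and 3 in kidney; of the 8 cell cycle genes, 5 passed in 16.113 tumours and 0 in J558L tumours.

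Across the 4386 genes, changes in J558L tumours and in 16.113 tumours, which share no arrays, had r = 0.400 (rho = 0.318); genes are not independent replicates. All 24 genes past the test in J558L tumours had the same sign in 16.113 tumours. Of these, 11 were higher in both, where chance overlap would give 0.409, and 4 were lower in both, against 0.385; Irf4, Ifi207 and Sp140 were among the former and Exo1 and H2bc3 among the latter. MCA313 at 24 h and J558L tumours had r = 0.466 with 12 genes higher in both (0.0876 by chance), and MCA313 at 24 h and 16.113 tumours r = 0.384 with 15 (0.613 by chance). J558L tumour and kidney had r = 0.370 with 10 higher in both (0.263 by chance). In these 3 pairs 0 genes were lower in both, and 28 of 30, 26 of 30 and 20 of 24 genes past the test in the first had the same sign in the second. Kidney and 16.113 tumours had r = 0.322 with 33 genes higher in both (1.84 by chance), 7 lower in both (3.22 by chance) and 1 opposite, and 116 of 139 had the same sign. These chance counts take genes and comparisons as independent. All comparisons shared the estimate of spread of each gene, and related genes such as Ifi205 and Ifi207 were counted singly, so chance overlap may be higher.

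**Figure D3:**
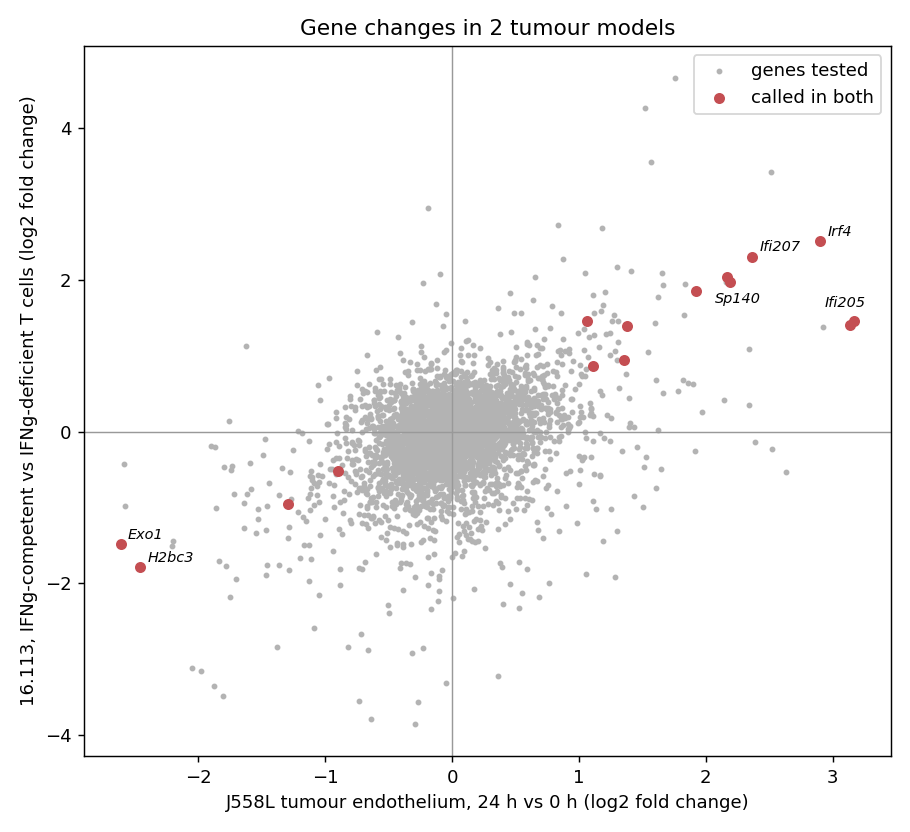
Log2 fold change in J558L tumour endothelium at 24 h (horizontal axis) against that in 16.113 tumours with competent over deficient T cells (vertical axis), 1 point per gene over 4386 genes; red points passed in both. All 15 red points lie in the quadrants of equal sign, and r = 0.400.

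Tests of the difference in response between models called no gene in limma. Between MCA313 and J558L tumours at 24 h, 131 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.363; between 16.113 and J558L tumours the figures were 275 and 0.211. In the latter Igtp (+1.90 ± 0.43, adjusted p = 0.211), Irf1 (+1.38 ± 0.31, adjusted p = 0.211) and Gm12250 (+1.99 ± 0.64, adjusted p = 0.454) did not pass. Socs3 (-1.08 ± 0.25, adjusted p = 0.211, 3 of 6 probe sets lower) and Id2 (-1.27 ± 0.33, adjusted p = 0.287) pointed the other way, also without passing. Both genes were called higher in the other 3 tumour comparisons and not in 16.113. The 5 GTPases differed as a list, higher in 16.113 (adjusted p = 1.54e-08; adjusted p = 0.130 with an estimated correlation), with 5 adjusted over the list alone. The models differ in tumour, mice, time and source of IFNγ together, and their arrays appear to have been normalized separately. With averaged probe sets 1 gene, Ctla4, chosen after its values were seen, differed between MCA313 and J558L (adjusted p = 2.94e-05). The size of that difference cannot be read, since all 11 of its probe sets lay below the array medians in MCA313 controls. Counts reached 3 without J558L tumour control replicate 2 for MCA313 against J558L; for 16.113 against J558L they reached 28 without competent replicate 1 and 4 without J558L tumour control replicate 2, and 1 with the arrays of these models alone.

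Among markers of other cells that the sort could hold, 5 macrophage and monocyte genes, 3 fibroblast genes and 6 B and plasma cell genes were tested as lists. In the 5 comparisons with a control group none of these lists was called, with adjusted p between 0.612 and 0.752 for macrophages, 0.196 and 0.851 for fibroblasts and 0.204 and 0.846 for B and plasma cells; of the last, Irf4 rose in the 4 tumour comparisons and Sdc1 fell in 16.113. The 4 neutrophil genes were called higher at 48 h than at 24 h in MCA313 tumours (adjusted p = 0.0215; adjusted p = 0.0743 with an estimated correlation), and that call ended in each of the 4 fits without 1 array and with the MCA313 arrays alone. Of the T and natural killer cell list, Cd247 and Prf1 were measured, too few for a test. Lists of leukocyte adhesion (7 genes), checkpoint and costimulation (4), quiescence and flow (4) and hypoxia (5) were not called in any of the 9 comparisons, with smallest adjusted p of 0.183, 0.362, 0.113 and 0.429, though Sele, Vsir and Id2 passed singly as given above.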

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

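The tests of explanation given here were chosen before their results were seen. Within the 5 arrays of 16.113 tumours with deficient T cells, 36 tests were made, of 35 named genes and the array medians, for an array standing apart from the rest; chance marks about 1 in 20, and 5 were marked by the gap to the next array as a share of the range. Ifi207 (0.871) and Irf1 (0.832) stood apart in replicate 2, at 9.14 and 10.90, and Dtl (0.746) in the same replicate at 11.03. Irf4 (0.808) stood apart in replicate 1 at 5.53, and Birc5 (0.814) in the same replicate at 8.88. Irf1 in that replicate 2 still lay below the 3 arrays with competent T cells, which read 11.99 to 12.44.

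Olfr1396 was called for a difference between the responses of J558L tumour and kidney (2.85 on the log2 scale). It read 3.33 to 3.58 in all tumour arrays, where a fall could not be read, so the call shows no difference between the tissues beyond the fall in kidney. The basement membrane and matrix list was called for a difference between these tissues (adjusted p = 0.00119; adjusted p = 0.0736 with an estimated correlation), and that call ended with averaged probe sets.

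The interferon-inducible GTPases were called higher in 16.113 than in J558L tumours as a list (adjusted p = 1.54e-08; adjusted p = 0.130 with an estimated correlation), with no member past the difference test over all genes. A candidate explanation is that the brightest probe sets neared the top of the scale in J558L arrays. The highest mean of these genes and Irf1 in any group, not in J558L groups alone, was 13.57. The highest deposited value was 14.34. Over the other 33 probe sets of the 6 genes the difference was 1.19 (95% interval 0.34 to 2.05), against 1.46 at the brightest ones. The lower bound of 0.341 lay narrowly above the 0.3 set beforehand, which argues against a ceiling as the whole source of such a difference. The tumour, the mice, the time, the source of IFNγ and, as it appears, the normalization differ between the models together and stay open as untested.

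Probe sets without a gene name were not used in the comparisons. Of 5264 such probe sets past the filter, 39 passed in MCA313 tumours at 24 h and 39 at 48 h, 8 in J558L tumours, 99 in J558L kidney and 100 in 16.113 tumours. Most of them were higher: 37, 39, 8, 94 and 70.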

How the results depend on the processing

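The leave-one-out fits of the agreement and of lists were chosen after seeing the data, all other alternatives before. The planned test of J558L tumour against kidney without induction was not run, since these arrays appear to have been normalized separately. Of 128 named results past the test, 118 stayed so without a filter, all 121 tested with a stricter filter, 115 with quantile normalization, 106 of 124 with averaged probe sets, 125 with a trended variance prior, 108 with array weights, 86 with the replicate block and 56 with the arrays of the models compared alone. Gene results kept their direction in all of these and in leave-one-out fits except Pecam1 in J558L tumours, not past the test, which lay between -0.0764 and 0.000695 (without control replicate 1) when 1 array was left out; list results never turned. The median change of all genes stayed within 0.1 of 0 as deposited and after quantile normalization. The counts that moved by over 1.5 times follow; their causes were not tested. Fitting fewer arrays leaves fewer degrees of freedom, which would not raise the J558L tumour count from 24 to 61. The shared estimate of spread also passes over differences between groups. The median deviation from the group mean was 0.238 to 0.284 in competent 16.113 arrays and 0.130 to 0.141 in J558L tumour arrays at 24 h. Sharing the estimate may thus raise the count for 16.113 and lower that for J558L tumours.

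With a stricter filter 47 genes passed for MCA313 at 24 h, 1 for 48 h against 24 h and 3 for tumour against kidney; quantile normalization gave 3 for the last. Averaged probe sets gave 140 (65 higher) and 174 (74 higher) for MCA313 at 24 h and 48 h, 1 between them, 109 (60 higher) for J558L tumour, 277 for kidney, 16 for tumour against kidney and 1 for MCA313 against J558L. The trended variance prior gave 0 for 48 h against 24 h and 5 for tumour against kidney. Array weights gave 60 for MCA313 at 24 h, 0 for 48 h against 24 h, 127 for J558L tumour, 242 for kidney, 16 for tumour against kidney and 77 (40 higher) for 16.113. Whether equal replicate numbers pair the samples is not known: the values showed no clear pairing, but groups shared only 2 or 3 numbers. With the replicate block 30 genes (26 higher) passed for MCA313 at 48 h, 0 for 48 h against 24 h and 10 for J558L tumour. It gave 80 (51 higher) for kidney, 2 for tumour against kidney and 158 for 16.113. The models' own arrays alone gave 1 and 4 for MCA313 at 24 h and 48 h, 0 between them, 61 for J558L tumour, 4 for tumour against kidney, 34 for 16.113 and 1 for 16.113 against J558L. The agreement r of 0.400 was 0.378 without a filter, 0.460 with a stricter one and 0.587 with averaged probe sets.

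Leaving out 1 array gave 12 to 49 genes for MCA313 at 24 h, 14 to 79 at 48 h, 0 to 7 between them, 3 to 18 for J558L tumour, 69 to 103 for kidney, 0 to 6 for tumour against kidney, 197 to 565 for 16.113, 0 to 3 for MCA313 against J558L, 0 to 28 for 16.113 against J558L and 0.343 to 0.399 for the agreement. Where 1 array remained in a group it was assumed to vary like the others. Over lists, 26 of the leave-one-out results lost their call and 137 did not, and 52 of the other alternatives lost it and 206 did not. Signal over background limits what dim probe sets can show.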

Other observations

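Of the tests given here, that of macrophage and fibroblast genes and that of T cell genes with Cd247 and Prf1 were chosen after the result was seen. Among genes higher in all 4 tumour comparisons (MCA313 at 24 h and 48 h, J558L and 16.113), 9 were found; those named here were chosen after their values were seen. Besides Irf4, Ifi205, Ifi207, Sp140, Gdap10 and C130026I21Rik they were Mndal, an Ifi200 family gene, Nampt, an enzyme gene of NAD synthesis, and Atxn7l1. Mndal was higher by 1.29, 1.29, 1.07 and 1.46 in these comparisons, Nampt by 1.49, 1.19, 1.38 and 1.39, and Atxn7l1 by 1.14, 1.18, 1.11 and 0.87. A further 9 genes were higher in 3 of the 4, none was lower in all 4, and H2bc3 was lower in 3. The overlap of the MCA313 time points is raised by their shared controls.

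Ctla4 rose in MCA313 tumours at 24 h and 48 h, and in J558L tumours, kidney and 16.113 it stood at -0.31, -0.49 and +0.56 without passing. A possible explanation is more T cells among the sorted cells, though how many passed the gate on CD31 and CD146 was not measured. The J558L mice were Rag-deficient, so Ctla4 in J558L tumours and kidney does not bear on T cells of the host. A list of 9 T cell genes, without Cd247 and Prf1, changed by 0.13 at 48 h. Its upper 95% bound of 0.317 lay below the 0.5 that had been set. That 0.5 was not derived from the T cells that the Ctla4 change would need. The bound thus limits the mean change of these genes and does not decide on T cells as the source. With Cd247 and Prf1 the 11 genes changed by 0.16 (upper 95% bound 0.385). Single genes stood higher without passing: Cd48 (+0.93), Ly9 (+0.58) and Cd247 (+0.62) at 48 h, and Cd247 (+0.79) at 24 h. T cells among the sorted cells, such as a small number or a kind rich in Ctla4, therefore stay open. Lcp2, at 12.21 in controls, is high in this tissue already and could hide a small share. Reads of another transcript by these probe sets and a response of endothelial cells themselves were not tested.

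The mean of 8 cell cycle genes fell in 16.113 tumours with competent T cells by 1.51 on the log2 scale (95% interval -2.07 to -0.96). As given above, not all of them passed singly, and the list call did not hold with an estimated correlation. A candidate explanation is fewer macrophages and fibroblasts among the sorted cells, though how many passed the gate on CD31 and CD146 was not measured. The fibroblast list was drawn up for sarcoma cells as well. The 8 marker genes of macrophages and fibroblasts changed by -0.43 (-0.94 to 0.08). They fell less than the cell cycle list, by 1.08 (95% interval 0.364 to 1.81). That interval excludes 0, but its lower bound lay under the 0.5 set for it. The conditions set for loss of such cells, an interval including 0 and a marker upper bound below 0, were not met either. Loss of such cells and a change within endothelial cells therefore cannot be told apart for these genes. Loss of other dividing cells was not tested. Quality of the 3 competent arrays was not tested either.

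Of the 56 splits of the 16.113 arrays into groups of 3 and 5, 1, the real one, gave as many as 323 genes. The highest of the others gave 84. A count that high thus came up in a share of splits below 0.05. Reading this as evidence of a group difference takes each array as its own animal, which the labels do not state. The splits do not bear on the size of the count, which was 34 with the 16.113 arrays alone. The 6 kidney arrays allow 10 splits, too few for such a share; the real one gave 139 genes and the highest other 4.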
